A study of Homo sapiens with 12 samples.

How the data were processed

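Gene expression was measured on Affymetrix expression arrays in HK-2 cells, an immortalised line of human renal proximal tubular epithelial cells. The 12 arrays fall into 4 groups of 3 arrays: control cells and cells given a low dose of Ota, each at 24 h and at 72 h. The labels call the 3 arrays of a group biological replicates and do not say what was shared between cultures, so the p-values measure the spread between these samples. According to the labels, cells were seeded on plates the day before exposure, exposed near confluency in a defined medium with epidermal growth factor, hydrocortisone and insulin, and set against cells given the vehicle. RNA was extracted on silica columns and labelled as biotinylated cRNA. The labels give no concentration and do not spell out Ota. OTA is the usual abbreviation of the nephrotoxic mycotoxin ochratoxin A, a name the labels do not write.

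The deposited values are on the log2 scale, 1 per probe set and array, and were made by the authors with GCRMA, per the submitters' processing notes. GCRMA subtracts background modelled from probe sequence, normalizes arrays by quantiles and summarises the probes of a set. Its version and settings were not given in the sources used here. Low values sit on a floor, so a fold change against a level near it is uncertain. Quantile normalization also brings the arrays close to a common distribution, so a change of all RNA in 1 direction is hard to see in these values. The deposited values do not share a distribution exactly: the upper quartile over all probe sets ranged from 6.89 to 7.11 between arrays. Arrays have no read depth, and the number of arrays limits the precision.

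The table held 54675 probe sets, of which 62 control probe sets were left out of tests. Gene names came from the platform annotation and were updated through gene identifiers with a RefSeq gene table of assembly GRCh38.p14, used for names alone. Exactly 1 gene symbol was paired with 41091 probe sets: 41037 were updated and 54 kept the platform's symbol. Several symbols were paired with 1801 probe sets and none with 11721, and no gene was named from either kind. Each of the 19775 genes was represented by its probe set with the highest mean over the 12 arrays. A gene was tested where that probe set was above a log2 value of 4 on at least 3 arrays, which left 10699 genes. Of these, 7272 had more than 1 probe set, and 664 were read from a probe set of the kind whose probes can match other transcripts.

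Each gene was fitted with 1 mean per group over all 12 arrays in limma 3.58.1 under R 4.3.3, with lmFit and eBayes at default settings and Benjamini-Hochberg adjustment. The residual degrees of freedom were 8 and the prior degrees of freedom 3.31. A gene was called changed at an adjusted p below 0.05. The comparisons were Ota against control at 24 h, Ota against control at 72 h, the difference of those responses, and control cells at 72 h against 24 h. The change from 24 h to 72 h in Ota cells was added after seeing the data. Errors of log2 fold changes are the fit's standard errors (SE), and errors of levels are standard deviations (SD) over 3 arrays. Tables were read with data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

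Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists with at least 5 genes tested. The same test with an estimated correlation and fry, which asks whether a list's genes moved on balance in 1 direction, were run beside it. The 30 lists, with 666 genes of which 599 were named and 488 tested, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. They cover DNA replication, mitosis, histones, p53 targets, apoptosis regulators, ATF4 and integrated stress response targets, endoplasmic reticulum chaperones and the unfolded protein response, heat shock response, NRF2 targets, aryl hydrocarbon receptor targets, metallothioneins and zinc response, hypoxia and glycolysis, mitochondrial respiratory chain, fatty acid oxidation and PPAR targets, cholesterol synthesis, ribosome biogenesis, cytosolic ribosomal proteins, autophagy and lysosome, NF-kB and inflammatory cytokines, interferon-stimulated genes, immediate-early genes and MAPK feedback, extracellular matrix and epithelial-mesenchymal transition, tight and adherens junctions and cytoskeleton, proximal tubule transport and differentiation, kidney injury markers, and markers of podocytes, fibroblasts, endothelial cells, leukocytes, and distal nephron and collecting duct.

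The rule named, for each Ota comparison, the 7 largest rises and 7 largest falls among changed genes whose Ota arrays all lay on 1 side of the control arrays. It also took up to 3 changed members of each list by smallest p, and HAVCR1, LCN2, CDKN1A and HMOX1 whatever their values. For the difference of responses and for the control cells over time it took the 4 largest values in each direction. The genes reported were narrowed after their values were seen, to at most 2 members of a list that passed and 1 member, with an adjusted p below 0.001, of a list that did not. Members named because they went against their list (H2AX, STC2, MT1M, TM7SF2 at 72 h, RFC4 at 72 h, SLC30A1 at 72 h and in control cells, and SESN1 in Ota cells over time) and the 8 genes plotted array by array were chosen after their values were seen.

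On simulated data with 200 changed genes among 10699, the same fit recovered 83.6% of genes changed by a factor of 2 for Ota at 24 h and 77.6% for Ota at 72 h. For the difference of responses it recovered 58.2%, and for control cells over time 89.6%. False calls made up 9.09%, 4.35%, 5.22% and 6.47% of the calls, in that order. Of genes changed by a factor of 1.5 it recovered 43.3%, 53.7%, 8.96% and 50.7%, in the same order. The simulated noise was independent between genes. Far fewer genes changed than in the data, where 21.3% to 46.4% did in these comparisons, so these shares need not hold there.

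The replicate numbers of the labels are shared between groups. Deviations from the group means of arrays with the same number correlated at r = 0.323 to 0.455 between control and Ota cells at 24 h, against -0.286 to -0.079 for other numbers, so the numbers were taken to pair these arrays. Between control and Ota cells at 72 h the same correlation was 0.067 to 0.268, and the numbers were not taken as pairs there. The main fit used no pairing at either time, so its p-values leave out what same-number arrays share. Counts with the replicate number as a block are given further on. No arrays held identical values, and the smallest median absolute difference between arrays of a group was 0.124. Alternatives covered the filter, 2 scalings (quantile normalization repeated over the 12 arrays, and each array shifted to a common median), the variance model, a replicate block, the samples in the fit, the choice of probe set, stricter thresholds, and each array left out in turn. The setting with all probe sets took each gene's probe set with the smallest p, separately in each comparison and without correcting for that choice. A gene's values at 24 h and 72 h can then come from different probe sets.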

Results

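HK-2 cells, an immortalised human renal proximal tubular epithelial line, were profiled after a low dose of Ota or its vehicle for 24 h or 72 h. There were 3 arrays in each of the 4 groups. The wider study set out to find expression signatures of toxicity among 9 compounds, several doses and several times, of which 1 dose of 1 compound is described here. Arrays of the same group correlated at r = 0.986 to 0.994 across the genes tested. The first principal component of the 10699 genes held 49.1% of the variance and the second 24.5%. As a sign of RNA quality, the log2 difference between the 3' and 5' actin control probe sets was 1.01 ± 0.21 (SD, n = 3) in control cells and 1.17 ± 0.12 in Ota cells at 24 h. At 72 h it was 1.18 ± 0.17 in control cells and 1.28 ± 0.08 in Ota cells. Most markers of other cell types were not above the filter: 3 of 10 fibroblast, 1 of 10 endothelial, 0 of 9 leukocyte and 2 of 12 distal nephron markers were, and the median log2 value of each list was at most 2.90. Of podocyte markers 6 of 8 were above the filter, and their median was 5.14 in control and 5.26 in Ota cells at 24 h and 4.91 and 4.94 at 72 h. Genes of proximal tubule transport and differentiation were also low, with 9 of 30 above the filter and medians of 2.70 to 2.71 in the groups. These levels therefore do not establish which cell type the cells resembled.

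The comparison at 24 h asked what a day of low-dose Ota changed. The largest rise was in H2AC6, a core histone gene, from 4.74 ± 0.94 (SD, n = 3) in control cells to 10.2 ± 0.37 in Ota cells, which is 45.4-fold. H2BC4, another core histone gene, rose 10.4-fold from a control level of 3.46 near the floor. DDX5, an RNA helicase gene read here from its single probe set with 1 symbol, rose 9.02-fold. The long non-coding RNA genes LINC01963 and MGC16275 rose 16.7-fold and 22.3-fold, and ADM5 and GCNA rose 10.1-fold and 8.63-fold. IFI35, an interferon-induced gene, fell by 4.49 ± 0.31 on the log2 scale (SE, n = 3 per group) to 2.52, which is at the floor, so the size of this change is uncertain. IFFO1 fell by 3.88 ± 0.29 to the same floor. NFE2L3, a transcription factor gene, fell by 3.38 ± 0.30, GYS1, which encodes a glycogen synthase, by 3.17 ± 0.23, and SPICE1, TLCD1 and LINC00472 by 3.25 ± 0.40, 3.25 ± 0.48 and 3.24 ± 0.39. ADM5 in control cells, at 3.75, and SPICE1 and LINC00472 in Ota cells, at 3.34 and 3.67, were also near the floor, which limits their sizes, and SPICE1 was at -1.61 with the mean of its probe sets. H2AC6, MGC16275, LINC01963, NFE2L3 and TLCD1 had at least 1 array below 4 in the lower group, so their sizes depend on the floor as well, and H2AC6 at 24 h ranged from 5.01 to 5.94 on the log2 scale over the settings and arrays left out. The adjusted p of these 14 genes in limma ranged from 2.28e-07 for DDX5 to 0.000412 for TLCD1, and for each the 3 Ota arrays lay on 1 side of the 3 control arrays.

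Histone genes were higher at 24 h: 6 of 9 rose, 1 fell and 2 did not pass, with a median of 1.17 (limma camera, adjusted p = 2.23e-05), or 0.36 without the filter (adjusted p = 0.00144). The call was lost at adjusted p = 0.481 with an estimated correlation, and adjusted over the list alone 7 rose and 1 fell. H2BC12 rose 3.72-fold (adjusted p = 1.32e-05, limma). The member that fell was H2AX, by 0.48 ± 0.09, which encodes a histone variant phosphorylated at DNA breaks. DNA replication genes moved the other way: 13 of 32 fell and 0 rose, with a median of -0.32 (camera, adjusted p = 0.0075). The call was lost at adjusted p = 0.972 with an estimated correlation, and 14 fell adjusted over the list alone. RFC4, a subunit of the clamp loader, fell by 2.16 ± 0.13 and GINS2, a subunit of the replicative helicase, by 1.51 ± 0.13 (limma, adjusted p = 1.02e-06 and 1.45e-05). GINS2 was at -0.63 with the mean of its probe sets. Of 8 metallothionein and zinc response genes 7 fell and 1 rose, over all genes and adjusted over the list alone, with a median of -0.61 (camera, adjusted p = 0.0383). The call was lost at adjusted p = 0.972 with an estimated correlation, and was 0.062 with the replicate number as a block. Over the settings tried, its adjusted p ranged from 0.000222 to 0.972, and it was 0.0697 without control 24 h replicate 2 and 0.117 without Ota 24 h replicate 3. MT1E, which encodes a metal-binding protein, fell by 0.64 ± 0.08 (limma, adjusted p = 0.000194). MT1E, MT1F, MT1G and MT2A were read from probe sets of the kind whose probes can match other transcripts. Changes of these related genes may therefore not be separate readings, at 24 h or in the other comparisons. The list member that rose was SLC30A1, a zinc exporter gene (0.52 ± 0.07, limma, adjusted p = 0.000282), but another of its probe sets went the other way by -0.89. The mean of its 3 probe sets was at -0.12 (limma, adjusted p = 0.333, in a range of 2.96e-05 to 0.333 over its settings).

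Single members of lists that did not pass also changed at 24 h. TP53I3, a p53-inducible oxidoreductase gene, fell by 2.48 ± 0.16, within a list of p53 targets in which 5 of 23 fell and 1 rose (4 and 4 with each array shifted to a common median). CDKN1A, the p53 target that encodes a cyclin-dependent kinase inhibitor, was at 0.25 ± 0.12 (limma, adjusted p = 0.14) and passed at 0.0315 when each array was shifted to a common median, in a range of 0.0315 to 0.373 over its settings. TM7SF2, a sterol reductase gene, fell by 1.96 ± 0.23, DDIT4, an inhibitor of mTOR signalling, by 1.62 ± 0.13, and ISG15, an interferon-induced ubiquitin-like gene, by 1.19 ± 0.16. Among interferon-stimulated genes 7 of 21 fell and 1 rose, and among immediate-early genes 5 of 18 fell and 0 rose, including IER2 by 1.10 ± 0.10. NQO1, a quinone reductase gene induced through NRF2 and the aryl hydrocarbon receptor, fell by 0.92 ± 0.15, while 5 of the 27 NRF2 targets rose and 1 fell (8 and 1 with each array shifted to a common median). AURKB, a mitotic kinase gene, fell by 1.08 ± 0.14, but its other probe set was at 0.26 and the mean of both at -0.41 (limma, adjusted p = 0.239, in a range of 0.000131 to 0.239 over its settings). Further falls were in ATG7, an autophagy gene, by 1.08 ± 0.16, CASP9, an initiator caspase gene, by 0.96 ± 0.15, ECI1, a fatty acid oxidation gene, by 0.75 ± 0.09, and NES, which encodes the filament protein nestin, by 0.72 ± 0.11. DNAJB4, a heat shock co-chaperone gene, rose by 0.66 ± 0.09. With the mean of a gene's probe sets ATG7 was at -0.44, CASP9 at -0.44 and NES at -0.35, with the calls kept, and another probe set of ATG7, at 0.10, did not pass. The adjusted p of the changed genes named here was at most 0.000808 in limma. The other fixed kidney genes did not pass: HAVCR1, a tubular injury marker, was at 0.11 ± 0.19, LCN2, another, at -0.02 ± 0.46 and HMOX1, a haem-degrading stress gene, at -0.20 ± 0.13. Over the settings tried, with each array left out among them, HAVCR1 at 24 h ranged from -0.02 to 0.36, LCN2 from -0.25 to 0.30 and HMOX1 from -0.27 to -0.07, and none passed.

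In total 3317 genes changed at 24 h, 1010 higher and 2307 lower in Ota cells, of which 202 and 558 changed at least 2-fold. The 3 Ota and 3 control arrays did not overlap in 4569 of 10699 genes, where chance gives 10%. The direction of the calls depended on the scaling. With each array shifted to a common median, 1881 were higher and 1697 lower, and the median of all genes moved by 0.12, from -0.06 to 0.07. With quantile normalization repeated, 1126 were higher and 2168 lower, and with all probe sets 1694 and 2615. The medians of the 3 lists that passed kept their signs: after the shift they were 1.29 for histones, -0.19 for DNA replication and -0.48 for metallothioneins. The other 23 lists had adjusted p of 0.331 or more in camera, and adjusted over the list alone their counts differed by at most 2. The list median, mean and test differed in sign for 11 of the 26 lists, none of them among the 3. Probe sets designed on expressed sequence tags rose more often (14.4% of 3662) than those designed on RefSeq mRNAs (6.05% of 3721).

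**Figure D1:**
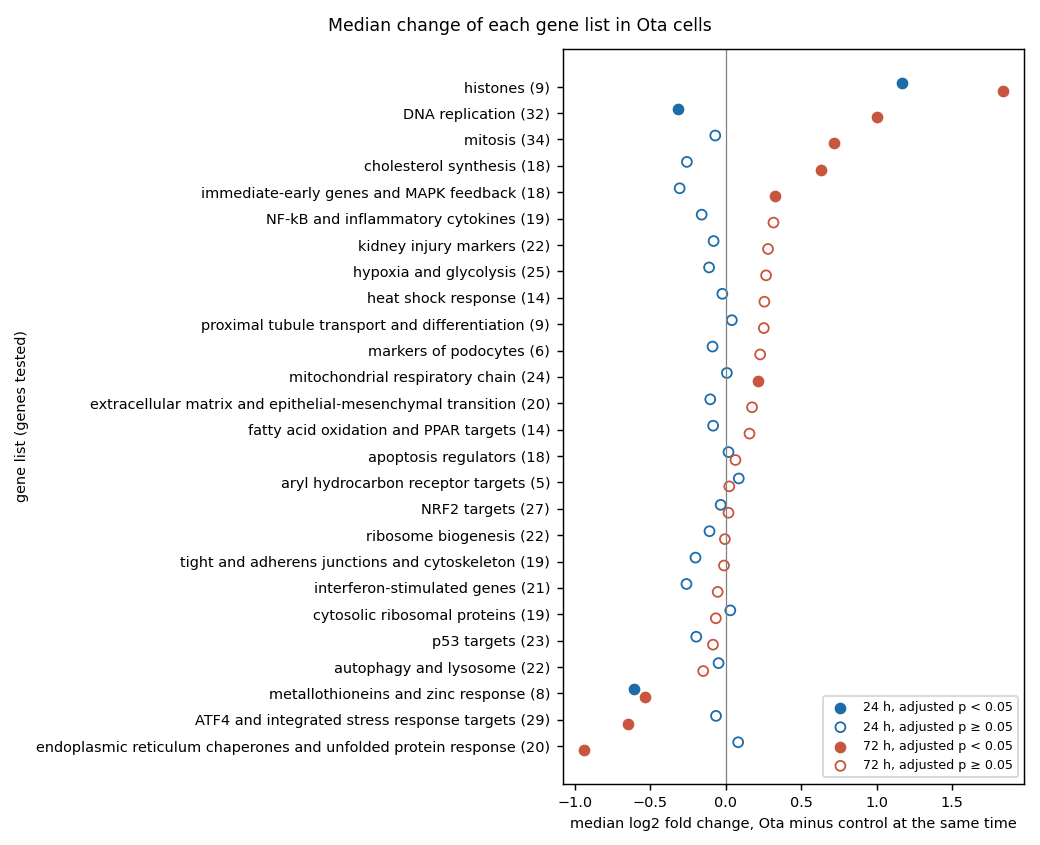
Median log2 fold change of each gene list in Ota cells against control cells of the same time (horizontal axis), at 24 h in blue and at 72 h in red, 1 line per list with the number of genes tested, filled where the limma camera test passed with its preset correlation. Histones had the highest median plotted at both times (1.17 and 1.84, or 0.36 and 1.21 without the filter) and endoplasmic reticulum chaperones the lowest at 72 h (-0.94); at 24 h small medians of lists that did not pass, such as NRF2 targets and mitosis, change sign when arrays are shifted to a common median.

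The comparison at 72 h asked the same of cells exposed for 3 days. Genes said to rise or fall in it were higher or lower in Ota than in control cells at 72 h. This is not a change over time. DNA replication genes were higher: UHRF1, which helps copy DNA methylation, rose 3.78-fold (log2 fold change 1.92 ± 0.10, SE, n = 3 per group) and DTL, a replication licensing control gene, 3.28-fold. The mitotic genes ANLN and CDCA8 rose 2.44-fold and 1.95-fold. Endoplasmic reticulum chaperone genes were lower: HYOU1 fell by 2.04 ± 0.23 and HSP90B1 by 1.61 ± 0.20. FDPS and EBP, enzyme genes of cholesterol synthesis, rose 2.33-fold and 1.69-fold, with EBP at a log2 value of 0.44 by the mean of its probe sets, of which another, at 0.37, did not pass. HAVCR1, the tubular injury marker, rose 3.22-fold, from 9.84 ± 0.28 (SD, n = 3) to 11.5 ± 0.06. The limma adjusted p of these 9 genes was at most 0.000282, and for each the 3 Ota arrays lay on 1 side of the 3 control arrays.

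The largest rises at 72 h were in DHRS2, a dehydrogenase gene that rose 19.4-fold from 2.82 at the floor, and in MGC16275, at 17.3-fold. Histone genes were again among them: H2BC4 rose 9.72-fold from 3.07 near the floor, H1-2, a linker histone gene, 9.07-fold from 3.51, also near the floor, and H2AC6 8.59-fold. IER5L rose 8.84-fold on its brightest probe set, while another of its probe sets, at 0.44, did not pass. EFCAB13-DT, a non-coding RNA gene, rose 7.67-fold. The largest fall was in IFFO1, by 4.28 ± 0.29 to the floor at 2.42, and ALDH1L2, a mitochondrial folate enzyme gene, fell by 3.09 ± 0.41. LAMP3, a lysosomal membrane gene, fell by 3.08 ± 0.48 and NEURL2 by 2.73 ± 0.21, both to levels near the floor. BEX2 fell by 2.56 ± 0.22, RALY-AS1, an antisense RNA gene, fell by 2.54 ± 0.22 to the floor and KDELR3, which encodes a receptor that returns proteins to the endoplasmic reticulum, fell by 2.50 ± 0.13. With the mean of a gene's probe sets the log2 values were 1.79 for IER5L, 1.46 for EFCAB13-DT, -1.50 for ALDH1L2 and -1.59 for KDELR3, with the calls kept, and another probe set of KDELR3, at 0.04, did not pass. The limma adjusted p of these 14 genes was at most 0.000725.

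DNA replication showed the smallest list p at 72 h: 29 of 32 genes rose and 1 fell, with a median of 1.00 (camera, adjusted p = 1.95e-18). The call was lost at adjusted p = 0.0831 with an estimated correlation, and adjusted over the list alone 30 rose and 1 fell. The gene that fell was RFC4, by 0.89 ± 0.13. Mitosis followed, with 28 of 34 higher, 0 lower and a median of 0.72 (camera, adjusted p = 2.02e-11; adjusted p = 0.371 with an estimated correlation), and 30 higher adjusted over the list alone. All 9 histone genes rose, over all genes and adjusted over the list alone, with a median of 1.84, or 1.21 without the filter (camera, adjusted p = 1.11e-09 and 3.72e-12; adjusted p = 0.0831 with an estimated correlation), among them H2BC6 at 3.58-fold. H2BC6 and H2BC5 were read from probe sets of the kind whose probes can match other transcripts. Changes of these related genes may therefore not be separate readings, at 72 h or in the other comparisons. Cholesterol synthesis had 12 of 18 higher and 1 lower (camera, adjusted p = 1.19e-05; adjusted p = 0.371 with an estimated correlation), and 14 higher and 1 lower adjusted over the list alone. The member that fell was again TM7SF2, by 0.94 ± 0.23. The respiratory chain list had 6 of 24 higher and 0 lower, also adjusted over the list alone, with a median of 0.22, or 0.34 with the mean of a gene's probe sets (camera, adjusted p = 0.00518; adjusted p = 0.304 with an estimated correlation). SDHA and NDUFV2, subunits of complexes of that chain, rose 1.46-fold and 1.34-fold. Immediate-early genes had 6 of 18 higher and 0 lower, also adjusted over the list alone (camera, adjusted p = 0.0205; adjusted p = 0.371 with an estimated correlation), with DUSP1 and KLF6 at 1.42-fold and 1.57-fold. On the log2 scale DUSP1 was at 0.26 with the mean of its probe sets, of which another, at 0.33, did not pass. KLF6 was at 1.14 on its probe set with the smallest p. Over the list's settings that adjusted p ranged from 0.000319 to 0.371, and it was 0.0788 without control 72 h replicate 2 and 0.0661 without Ota 72 h replicate 3.

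Endoplasmic reticulum chaperones and the unfolded protein response were lower in Ota than in control cells at 72 h. Of 20 genes 19 were lower and 0 higher, with a median of -0.94 (camera, adjusted p = 1.69e-10, or adjusted p = 0.333 with an estimated correlation). Adjusted over the list alone 20 were lower. From 24 h to 72 h the list rose in both, with medians of 2.24 in control and 0.89 in Ota cells. Of 29 ATF4 and integrated stress response targets 20 fell and 1 rose, also adjusted over the list alone, with a median of -0.65 (camera, adjusted p = 2.36e-08; adjusted p = 0.333 with an estimated correlation). WARS1, a tRNA synthetase gene, fell by 1.76 ± 0.21 and DDIT4 by 1.53 ± 0.13, and STC2, a secreted glycoprotein gene, rose by 1.03 ± 0.36 (limma, adjusted p = 0.0488). Metallothioneins had 6 of 8 lower and 2 higher, also adjusted over the list alone, with a median of -0.53 (camera, adjusted p = 0.0357; adjusted p = 0.371 with an estimated correlation). MT1E fell by 0.57 ± 0.08 and MT1G by 0.58 ± 0.10 (-0.31 with the mean of its probe sets), and MT1M and SLC30A1 rose by 0.41 ± 0.11 and 0.31 ± 0.07. Over its settings the list's adjusted p ranged from 0.00151 to 0.371. It was 0.0533 without control 72 h replicate 1, 0.0676 without Ota 72 h replicate 2, 0.0622 with quantile normalization repeated and 0.0575 with arrays shifted to a common median.

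Other kidney and stress genes changed at 72 h within lists that did not pass. Among kidney injury markers 6 of 22 rose and 2 fell (camera, adjusted p = 0.0985), and KRT18, an epithelial keratin gene, fell by 0.87 ± 0.11. LCN2 at 72 h was at -1.02 ± 0.46 (limma, adjusted p = 0.112) and -1.47 without control 72 h replicate 1 (adjusted p = 0.0333), within a range of 0.0121 to 0.381, and of -1.47 to -0.57 in value, over its settings. CDKN1A rose 1.71-fold and TP53I3 fell by 1.26 ± 0.16, with 3 of 23 p53 targets higher and 3 lower. HMOX1 was at -0.22 ± 0.13 (-0.34 to -0.11 over its settings) and NQO1 fell by 1.19 ± 0.15, with 2 of 27 NRF2 targets higher and 3 lower, and 1 of 5 aryl hydrocarbon receptor targets higher and 1 lower. Hypoxia and glycolysis genes had 12 of 25 higher and 4 lower, with ENO2, a glycolytic enzyme gene, at 2.11-fold, and heat shock genes 5 of 14 higher and 0 lower (1 lower with quantile normalization repeated), with CRYAB, a small heat shock protein gene, at 1.97-fold. Extracellular matrix genes had 5 of 20 higher and 3 lower, and LOX, which cross-links collagen, fell by 2.10 ± 0.32. Fatty acid oxidation had 2 of 14 in each direction, and ACADVL, an acyl-CoA dehydrogenase gene, fell by 1.22 ± 0.20. Inflammatory genes had 7 of 19 higher and 1 lower, the chemokine gene CXCL3, which fell by 1.15 ± 0.15. Interferon-stimulated genes had 4 of 21 higher and 2 lower (4 and 4 with quantile normalization repeated), with ISG15 falling by 1.10 ± 0.16, and apoptosis regulators 2 of 18 in each direction, with BID, a pro-apoptotic gene, at 1.83-fold.

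The remaining lists did not pass at 72 h. Counts of higher and lower genes were 0 and 3 of 22 for autophagy and lysosome, 0 and 0 of 22 for ribosome biogenesis, 0 and 0 of 19 for cytosolic ribosomal proteins, 2 and 5 of 19 for tight and adherens junctions and 3 and 0 of 9 for proximal tubule transport. Of podocyte markers 1 of 6 rose, NES, at 1.89-fold. Lists with fewer than 5 genes were not tested: of 3 fibroblast markers 2 rose, among them the proteoglycan gene LUM at 3.21-fold, of 2 distal nephron markers and 1 endothelial marker 0 changed, and of leukocyte markers 0 were above the filter. With the mean of a gene's probe sets NES was at a log2 value of 0.45 and LUM at 0.84. The lists that did not pass had camera adjusted p of 0.0621 or more, and adjusted over the list alone their counts differed by at most 2. The median, mean and test differed in sign for 2 of the 26 lists, none of which passed. In total 3421 genes changed at 72 h, 1827 higher and 1594 lower, with 358 and 262 by at least 2-fold. Which direction held more genes depended on the scaling, with 1623 higher and 1930 lower when quantile normalization was repeated and 1768 and 1730 with each array shifted to a common median. In all, 5498 genes showed no overlap between the 3 Ota and 3 control arrays, where chance gives 10%.

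**Figure D2:**
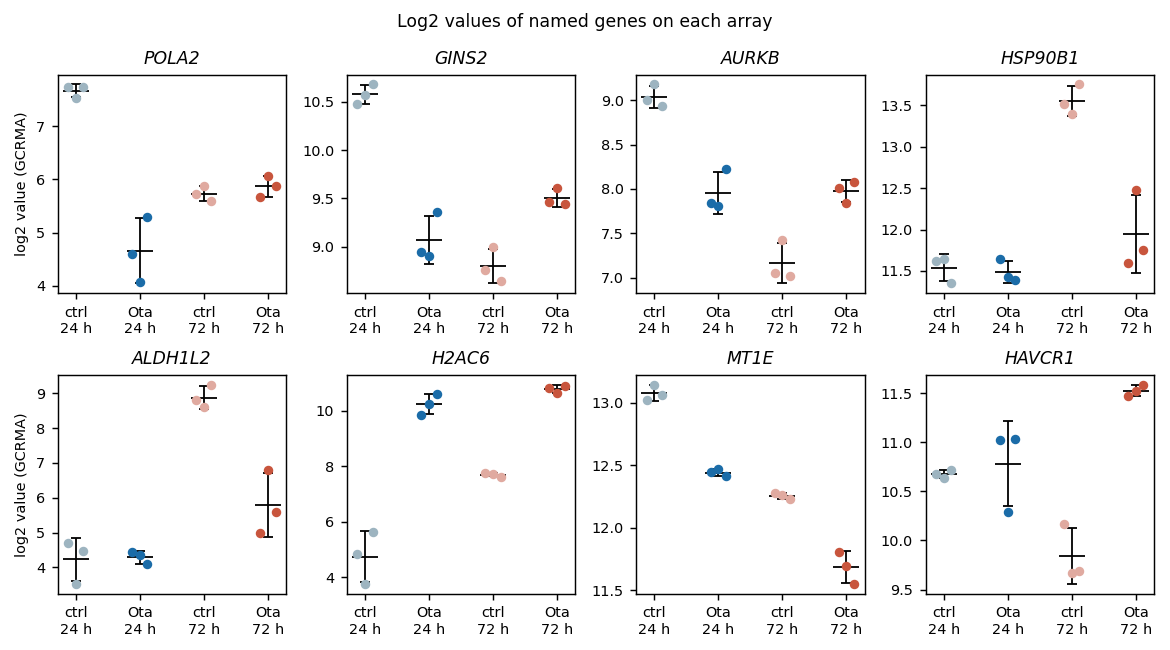
Log2 expression of 8 genes on each array (vertical axes, which do not start at 0 and differ between panels) in control and Ota cells at 24 h and 72 h, with dots for arrays, and a long bar and whiskers for the mean ± SD of 3 arrays. HSP90B1 was at 13.6 in control cells and 11.9 in Ota cells at 72 h, and H2AC6 was above its control arrays in all 3 Ota arrays of each time.

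The difference of the responses asked whether Ota acted differently at 72 h than at 24 h, each against its own controls. All 32 DNA replication genes had a higher response at 72 h, over all genes and adjusted over the list alone, with a median difference of 1.38 (camera, adjusted p = 2.24e-23; adjusted p = 0.0859 with an estimated correlation). POLA2, a primase complex gene, differed by 3.14 ± 0.34 (SE, n = 3 per group), WDR76 by 3.06 ± 0.53 and GINS4, a helicase subunit gene, by 3.05 ± 0.68. POLA2 fell from 7.66 to 4.66 at 24 h and was at 5.73 and 5.87 at 72 h. KRT20, a keratin gene, had the largest difference, at 3.39 ± 0.64. In the other direction were ALDH1L2 at -3.15 ± 0.57, LAMP3 at -3.12 ± 0.68, LINC01963 at -2.69 ± 0.46 and ADCY10P1 at -2.50 ± 0.33, with LAMP3 and ADCY10P1 near the floor in 3 of the 4 groups, and GINS4 near it, at 3.83, in control cells at 72 h. ALDH1L2 and LINC01963 each had 1 of 12 arrays below 4. With the mean of a gene's probe sets POLA2 was at 1.17 and ALDH1L2 at -1.53. The limma adjusted p of these 8 genes ranged from 0.000227 to 0.0099.

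Mitosis had 25 of 34 genes with a higher response at 72 h and 0 with a lower one (camera, adjusted p = 4.4e-10; adjusted p = 0.374 with an estimated correlation), and 31 higher adjusted over the list alone. Cholesterol synthesis had 14 of 18 higher and immediate-early genes 9 of 18, with 0 lower in both (camera, adjusted p = 5.15e-06 and 0.00055; adjusted p = 0.374 with an estimated correlation for both). Adjusted over the list alone the counts were 14 and 10. Endoplasmic reticulum chaperones had 14 of 20 lower, or 16 adjusted over the list alone, and ATF4 targets 7 of 29, or 7 adjusted over the list alone (13 with each array shifted to a common median), with 0 higher in both (camera, adjusted p = 1.87e-11 and 3.22e-07; adjusted p = 0.374 with an estimated correlation for both). Cytosolic ribosomal proteins had a median of -0.09 (-0.24 with arrays shifted to a common median) with 0 of 19 genes changed, also adjusted over the list alone (camera, adjusted p = 0.0356; adjusted p = 0.374 with an estimated correlation). That p was 0.0912 without a filter and 0.246 with quantile normalization repeated, and 0.059, 0.0612, 0.0558, 0.0533 and 0.0757 without control 24 h replicate 1, Ota 24 h replicates 2 and 3, control 72 h replicate 3 and Ota 72 h replicate 3. The range over its settings was 0.00107 to 0.374. No list in any comparison passed camera with an estimated correlation, while fry passed 8 lists at 24 h, 16 at 72 h, 14 for the difference and 18 in control cells over time. The other 19 lists had adjusted p of 0.101 or more, and the median, mean and test differed in sign for 4 of the 26 lists, none of which passed.

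In total 2278 genes differed in response, 1659 with a higher and 619 with a lower value at 72 h. With each array shifted to a common median the numbers were 1164 and 1184, with 1783 of the genes shared, and the median of all genes moved by -0.14, from 0.09 to -0.05. With quantile normalization repeated they were 1397 and 843. The medians of the 7 lists that passed kept their signs, and after the shift the median of DNA replication was 1.24 and that of endoplasmic reticulum chaperones -1.10. Of the genes changed at both times, 1192 changed in the same direction (415 higher, 777 lower) and 231 in opposite directions (41 higher then lower, 190 lower then higher). Independent lists of these sizes would share 172.5, 343.7, 150.5 and 394 genes in that order. The 231 genes in opposite directions became 339 with the replicate number as a block, 379 with the block within each time point and 153 without Ota 24 h replicate 2. With all probe sets they were 518, but there the directions at 24 h and 72 h can come from different probe sets of a gene. The log2 fold changes at both times correlated across genes at r = 0.444 (Spearman rho = 0.365), where genes are not independent replicates, and the comparisons had separate controls.

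**Figure D3:**
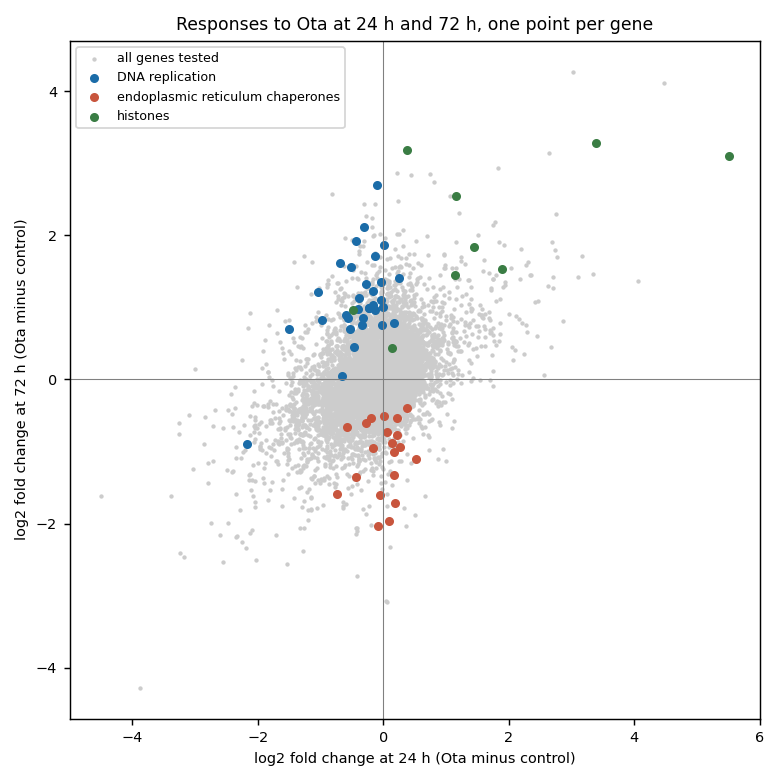
Log2 fold change with Ota at 24 h (horizontal axis) against that at 72 h (vertical axis), 1 point per gene over 10699 genes, with DNA replication, endoplasmic reticulum chaperone and histone genes coloured. DNA replication genes had a median of -0.32 at 24 h and 1.00 at 72 h, and histone genes had positive medians at both times, under both scalings too.

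Control cells also changed with time, which sets the background for the comparisons above. The stress genes INHBE, ATF3 and DDIT3, the last encoding the stress transcription factor CHOP, rose 48.2-fold, 46.0-fold and 37.9-fold from 24 h to 72 h, and ALDH1L2 rose 25.2-fold. TXNIP, a thioredoxin-binding gene induced by glucose, fell by 5.95 ± 0.22 on the log2 scale (SE, n = 3 per group), GAL, a neuropeptide gene, fell by 4.40 ± 0.46, SCN3A, a sodium channel gene, fell by 4.25 ± 0.18 and NCAPH, a condensin gene, fell by 3.37 ± 0.10. Levels near the floor limit the sizes for ATF3 (3.87 at 24 h), GAL (3.26 at 72 h) and SCN3A (2.56 at 72 h), and 1 array of ALDH1L2 was below 4. With the mean of a gene's probe sets the log2 values were 3.17 for ATF3, 2.01 for ALDH1L2, -2.19 for GAL and -2.12 for SCN3A. The limma adjusted p of these 8 genes was at most 1.99e-05. All 34 mitosis genes fell, with a median of -1.85, and 30 of 32 DNA replication genes fell and 0 rose, with a median of -1.44 (camera, adjusted p = 3.79e-21 and 3.81e-18; adjusted p = 0.219 and adjusted p = 0.181 with an estimated correlation). All 20 endoplasmic reticulum chaperone genes rose, with a median of 2.24, and 28 of 29 ATF4 targets rose and 0 fell, with a median of 1.95 (camera, adjusted p = 1.23e-13 and 1.29e-17; adjusted p = 0.228 and adjusted p = 0.219 with an estimated correlation). Adjusted over the list alone these 4 counts were 34, 30, 20 and 28. Of 8 metallothionein genes 7 fell and SLC30A1 rose, and of 24 respiratory chain genes 13 fell and 0 rose, with the same counts adjusted over the list alone (camera, adjusted p = 0.000293 and 0.00253; adjusted p = 0.219 with an estimated correlation for both). With either scaling repeated 1 respiratory chain gene rose. Cytosolic ribosomal proteins had 6 of 19 higher, 5 adjusted over the list alone, or 3 with quantile normalization repeated (camera, adjusted p = 0.0285; adjusted p = 0.385 with an estimated correlation). All 3 fibroblast markers fell. In total 4963 genes changed, 2434 higher and 2529 lower at 72 h (2545 and 2511 with each array shifted to a common median), and the other 19 lists had adjusted p of 0.201 or more.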

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

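The test of the slope between changes over time, the scaling test and the regroupings of arrays in this part were planned before their results were seen, and the comparison of 4 list medians with that slope was added afterwards.

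The response to Ota differed between 24 h and 72 h for 2278 genes by the test of the difference itself in limma. Of gene lists 7 differed in limma camera at its preset correlation, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.0859. Their median differences, 72 h minus 24 h, were 1.38 for DNA replication, 1.02 for cholesterol synthesis, 0.83 for mitosis and 0.71 for immediate-early genes. They were -0.95 for endoplasmic reticulum chaperones, -0.51 for ATF4 targets and -0.092 for cytosolic ribosomal proteins. Of the 73 genes named for the Ota comparisons and their difference, 52 differed between the times, 34 with a larger and 18 with a smaller value at 72 h. Over all genes tested 21.3% differed. A higher share among the named genes was built in, since the rule took large changes and 8 genes for their difference.

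The larger values at 72 h, as log2 differences from the response at 24 h, included many DNA replication and mitosis genes. They were 3.14 for POLA2, 3.06 for WDR76, 3.05 for GINS4, 2.35 for UHRF1, 2.21 for GINS2, 1.89 for AURKB, 1.85 for DTL, 1.30 for CDCA8, 1.27 for RFC4 and 1.18 for ANLN. The linker histone gene H1-2 differed by 2.80. Genes that had fallen far at 24 h and were lower by less at 72 h, whether or not they passed there, were IFI35 at 2.88, SPICE1 at 2.65, TLCD1 at 2.49, NFE2L3 at 1.76, TP53I3 at 1.22 and TM7SF2 at 1.02. KRT20 differed by 3.39, NES by 1.64, HAVCR1 by 1.58, ENO2 by 1.46, LUM by 1.40, CRYAB by 1.37, FDPS by 1.25, KLF6 by 1.12, EFCAB13-DT by 1.11 and EBP by 1.09. DUSP1 differed by 0.99, BID by 0.94, IER2 by 0.92, ATG7 by 0.90, SDHA by 0.81, IER5L by 0.51 and ECI1 by 0.42.

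The smaller values at 72 h were led by ALDH1L2 at -3.15, LAMP3 at -3.12, LINC01963 at -2.69, ADCY10P1 at -2.50, H2AC6 at -2.40 and NEURL2 at -2.30. The stress and chaperone genes HYOU1, WARS1 and HSP90B1 were at -1.96, -1.81 and -1.56. ADM5 was at -1.87, GCNA at -1.69, LOX at -1.68, DDX5 at -1.46, ACADVL at -1.12, BEX2 at -1.02, CXCL3 at -0.68, DNAJB4 at -0.52 and KRT18 at -0.48.

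Probe sets without a gene name, which no comparison of genes used, also changed: of 2063 above the filter, 564 changed at 24 h (385 higher, 179 lower) and 422 at 72 h (301 higher, 121 lower).

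Control cells lost DNA replication and mitosis expression and gained ATF4 target and chaperone expression between 24 h and 72 h, and the same 4 lists moved the opposite way in Ota cells against controls at 72 h. Both comparisons use the control arrays at 72 h, with opposite signs, so part of this opposite movement can be built in. Scaling between arrays was tested first, and all 8 combinations of 4 lists and 2 scalings kept the call at the preset correlation and its direction. The scalings moved the median of all genes at 72 h by only -0.047 (quantile) and -0.019 (shift). Camera compares a list with the other genes, so a shift of whole arrays could hardly change a call. The test therefore does not settle scaling. With quantile normalization repeated, the list medians were 0.98 for DNA replication, 0.70 for mitosis, -0.68 for ATF4 targets and -0.975 for chaperones. A candidate explanation for part of the pattern of these 4 lists is that the change over time that control cells showed was smaller in Ota cells across genes in general. Its test took the slope of the change over time in Ota cells on that in control cells, corrected for measurement error. Over the 10200 genes matched to no list by a current or older symbol, the slope was 0.457, and 0.417 to 0.489 with each array left out. Equal changes would give 1. The changes in Ota and control cells correlated at r = 0.561 across these genes. A slope below 1 also arises where changes are as large but differ between genes, so the slope alone does not show a general shrinkage. DNA replication fits the slope least, with a median change over time of -1.44 in control cells and 0.007 in Ota cells, where the slope would leave -0.66. Ota medians of -1.01 for mitosis, 1.29 for ATF4 targets and 0.89 for chaperones lay nearer to the -0.85, 0.89 and 1.03 it would leave. For the other lists that may mean slower ageing of the Ota cultures, for example through fewer cells or less use of medium, but neither was measured here and a direct effect of Ota on these genes stays open.

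Regrouping the arrays was planned as a test of chance. For the difference of responses, 2 of 100 regroupings of Ota and control arrays within each time, counting the real grouping among them, gave at least the real 2278 genes. These regroupings remove the effect of Ota at both times rather than make the responses equal, so the low share set in advance as a sign against chance was the wrong one, and they leave chance open. The highest other regrouping, with 4406 genes, swaps Ota and control at 1 time and so reads the sum of the responses; without it the highest was 1190. For Ota at 24 h (real 3317, highest other 0), Ota at 72 h (real 3421, highest other 1) and control cells over time (real 4963, highest other 0), the real split was 1 of 10, and 10 splits are too few for a share under 0.05. At 24 h, where the replicate numbers pair the arrays, the other splits among the 4 that part every pair also gave 0 genes.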

How the results depend on the processing

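No setting here was added after the result was seen except the change over time in Ota cells, which was not among the planned comparisons. All alternatives chosen in advance were run, and some named genes had no value under the stricter filter, without probe sets that can match other transcripts or with the mean of probe sets. Total counts of changed genes, and of genes changed in the same direction at both times, stayed within 1.5 times of those reported except under stricter thresholds, whose construction makes them smaller. With a log2 fold change of at least 1 they were 760 at 24 h, 620 at 72 h, 795 for the difference, 1181 for control cells over time and 184 for the overlap in the same direction, and at an adjusted p below 0.01 they were 2054, 1959 and 921, with an overlap of 603. Leaving out each array in turn gave 2507 to 3229 genes at 24 h, 2460 to 2968 at 72 h, 1555 to 2401 for the difference, 4289 to 4853 for control cells and 913 to 1247 for the overlap. Lists numbered 2 to 3, 8 to 13 and 6 to 9. Counts by direction moved further. The 231 genes changed in opposite directions became 518 with all probe sets, where the probe set of a gene can differ between the times. They became 379 with the block within each time point, 153 without Ota 24 h replicate 2, 8 with a log2 fold change of at least 1 and 71 at an adjusted p below 0.01. The 1010 genes higher at 24 h became 1881 with arrays shifted to a common median and 1694 with all probe sets, and the 619 with a lower response at 72 h became 1184 with that shift.

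With the replicate number as a block, limma called 3815 genes at 24 h, 3874 at 72 h, 2831 for the difference and 5419 for control cells. With the block within each time point they were 3940, 4080, 3022 and 5656. The overlap was 1424 and 1517. The block ended the call of metallothioneins at 24 h (adjusted p = 0.062) and no other list call, and LCN2 at 72 h gained one at -1.02 (0.0171, and 0.0121 within time points). At 72 h not every pair of control and Ota arrays with the same number correlated above 0.1. Between groups of different times same-number pairs correlated at 0.08 to 0.262, which hints at numbers shared across times, though the labels do not say so.

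Lists passing camera with an estimated correlation numbered 0, 0 and 0 at 24 h, 72 h and for the difference, and with fry 8, 16 and 14. Without a filter 12 lists differed, and 5 passed at 24 h with the mean of a gene's probe sets, and the cause was not tested. Of 98 results for named genes 92 kept their direction and side of the threshold under every alternative run for them and with each array left out. Of the other 6, HAVCR1 and LCN2 at 24 h did not pass under any setting but turned direction, from -0.021 to 0.356 and from -0.252 to 0.303. With the mean of a gene's probe sets SLC30A1 at 24 h turned to -0.12, since its probe sets disagree, and AURKB lost its call (-0.41). With arrays shifted to a common median CDKN1A at 24 h gained one (0.38), and LCN2 gained one without control 72 h replicate 1. The mean of a gene's probe sets moved 22 called gene values by more than 1.5 times and 20 of them kept their call. That mean includes probe sets below the filter. For GINS2, POLA2, ALDH1L2, EFCAB13-DT, SPICE1, NES, LUM, MT1G, GAL and SCN3A no other probe set was above the filter. Their smaller means can therefore reflect probe sets with low values, and not a disagreement as for SLC30A1 and AURKB. Levels near the floor limit the sizes for IFI35, IFFO1, ADM5, SPICE1, LINC00472, RALY-AS1, LAMP3, NEURL2, DHRS2, H2BC4, H1-2, ADCY10P1, GINS4, ATF3, GAL and SCN3A, and single arrays below 4 those for H2AC6, MGC16275, LINC01963, TLCD1 and ALDH1L2. NFE2L3 had 2 such arrays. Besides metallothioneins, H2BC6, HSP90B1, KRT18 and SDHA were named from probe sets whose probes can match other transcripts. For HSP90B1 another probe set also passed at 72 h, at -1.51.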

Other observations

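The comparison of Ota cells over time and the test of scaling on the direction of calls were chosen after the results they bear on were seen, as were 3 of the 4 definitions used for the kinds of probe set.

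In Ota cells, as in control cells, mitosis genes fell and stress genes rose between 24 h and 72 h. Of 34 mitosis genes 31 fell and 0 rose, with a median of -1.01 (limma camera, adjusted p = 2.29e-23; adjusted p = 0.301 with an estimated correlation), against a median of -1.85 in control cells. ATF4 targets had 26 of 29 higher with a median of 1.29 and endoplasmic reticulum chaperones 11 of 20 higher with a median of 0.89 (camera, adjusted p = 6.17e-14 and 4.32e-05; adjusted p = 0.301 and adjusted p = 0.557 with an estimated correlation). DNA replication genes, of which 30 fell in control cells, had 5 higher and 4 lower in Ota cells, and 3 higher and 9 lower with each array shifted to a common median. Cholesterol synthesis rose in 16 of 18 genes, inflammatory genes in 12 of 19, immediate-early genes in 10 of 18 and p53 targets in 9 of 23, with SESN1, a p53 target and stress gene, falling by 0.40. These 4 lists had camera adjusted p of 7.79e-06, 0.00287, 0.000598 and 0.0371, and adjusted p = 0.557, adjusted p = 0.557, adjusted p = 0.353 and adjusted p = 0.557 with an estimated correlation. Metallothioneins fell in 7 of 8 and respiratory chain genes in 4 of 24 (8 with each array shifted to a common median), with 0 higher in both (camera, adjusted p = 6.96e-08 and 0.00893; adjusted p = 0.22 and adjusted p = 0.353 with an estimated correlation). In the order named here, the counts adjusted over the list alone were 32, 29, 11, 5 and 4, 17, 14, 13, 9, 7 and 3. In total 3447 genes changed in Ota cells over time, 2378 higher and 1069 lower, but 1668 and 2001 with each array shifted to a common median and 1944 and 1395 with quantile normalization repeated.

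At 24 h probe sets designed on expressed sequence tags rose with Ota more often than those designed on RefSeq mRNAs, 14.4% against 6.05%, a difference seen before it was tested. The tags being dimmer does not account for it, since the difference matched on mean level was 8.55 ± 0.70 percentage points (SE), and 8.82, 13.1 and 13.8 under the other definitions. Nor do different genes carrying each kind: within 1741 genes with both kinds, the tag's probe set had the higher log2 fold change in 63.3% (SE 1.16), and it rose where the RefSeq one fell in 108 genes against 18 the other way. The SEs in this paragraph treat genes or probe sets as independent. All share the same arrays, so these SEs do not measure the spread between arrays. By array, the mean gap between the tag's probe set and the RefSeq one in these genes was -0.31 to -0.26 in control cells at 24 h. In Ota cells at 24 h it was -0.03 to 0.06. RNA integrity, read from the actin 3' to 5' difference, predicted 9.01% of the change, with an upper limit of 16.4%. The cause stays open and need not be Ota: in control cells over time 26.5% against 20.2% rose, with the tag's probe set higher in 61.8% of genes with both, and with Ota at 72 h the matched difference was 1.33 ± 0.889 points over genes and 3.97 ± 0.675 over probe sets, with the tag's higher in 55.1% (SE 1.19).

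More genes fell than rose with Ota at 24 h, 2307 against 1010. With each array shifted to a common median 52.6% of changed genes rose, against 30.4% as deposited, but the shift itself sets the shares near even, so this decides nothing. With quantile normalization repeated the excess stayed, at 1126 higher and 2168 lower. The excess also depended on the kind of probe set. Over genes, 6.05% rose and 23.2% fell on RefSeq mRNAs, against 14.4% and 18.9% on tags. Over all probe sets with 1 symbol, 6.47% rose and 22.2% fell on RefSeq mRNAs, but 19.4% rose and 15.5% fell on tags. Of probe sets without a gene name 385 rose and 179 fell. Whether the scaling of the arrays, the kind of probe set or a true loss of RNA from many genes lies behind the excess stays open.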
